A study of Mus musculus with 2 samples.

How the data were processed

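Open chromatin was measured by ATAC-seq, in which a transposase inserts adapters into accessible DNA, in limb tissue of mouse embryos at 11.5 days. Per the labels, there was 1 group with 2 biological replicates, a pool of limbs from 109 embryos (replicate 1) and a pool from 88 embryos (replicate 2), of both sexes. The labels did not say whether forelimbs, hindlimbs or both were taken.

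The deposited files were peak lists on the mm10 build, and they held no read counts, so the depth of each library is unknown. Per the file headers, the lists were made from filtered alignments. The aligner, the peak caller and their versions are not given in the sources used here. Each deposited list gave, for every summit, a signal value whose scale the authors did not state, taken here as enrichment over background, as the file format defines it. The deposited lists also gave a −log10 p and a −log10 q for each summit. A deposited ranked list gave a score and the −log10 of the irreproducible discovery rate (IDR). The IDR is a measure of how well the rank of a peak repeats between replicates. A score of 540 or more in that list was taken as past an IDR threshold of 0.05. The signal was compared within a list only.

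The 7 lists used were 3 of both replicates and 2 of each replicate. The main set was the conservative list of both replicates past the IDR threshold of 0.05, called the IDR list here. A larger IDR list and a list of peaks overlapping between replicates without an IDR threshold (the overlap list) served as alternatives. The larger list does not contain every region of the main one. Each replicate had its own IDR list and a list without an IDR threshold that the labels call pseudoreplicated, named its overlap list here. The lists hold several summits per interval, so overlapping intervals were merged into regions. All lists were read on 21 chromosomes (1 to 19, X and Y). The pooled pseudoreplicated list and the ranked lists of each replicate were left out because no comparison needed them, and the ranked list of both replicates was used only to look for regions absent from the IDR list.

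Genes came from GENCODE M21 on GRCm38 patch 6, with 21851 protein-coding genes. A region was at a promoter when it came within 500 bp of an annotated protein-coding start, and distal when it lay over 2000 bp from any annotated start. The share of regions at promoters was compared with the share of the genome in promoter windows by a two-sided exact binomial test. As a further background, the regions were moved along the chromosomes in 10 steps of 1 Mb. A distal region was assigned to the protein-coding gene with the nearest start. The territory of a gene is the stretch nearer to its start than to any other.

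The 16 gene lists were limb mesenchyme transcription factors, limb bud signalling, HoxA and HoxD genes 9 to 13, cartilage and joint, limb muscle precursors and muscle, endothelium, erythroid cells, macrophages, surface ectoderm, nerve and glial cells of the limb, central nervous system, liver, heart, photoreceptors, housekeeping, and olfactory and vomeronasal receptors. For promoters, each list was compared with all other genes by Fisher's exact test, two-sided. A second comparison used 10000 random lists matched in 20 bins on the observed over expected CpG frequency of the promoter, a permutation test. For distal regions, the mean count per gene was compared with 10000 random lists matched in 20 bins on territory length, a two-sided permutation test whose smallest possible p is 0.0002. Genes of a list are not replicates, so these p-values describe the list within this tissue and not variation between embryos.

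The 22 consensus sequences were counted in windows of 200 bp around the strongest summit of each distal region. The background was a flank window of the same size, 2 to 10 kb away (2000 to 10000 bp), with the nearest GC content and outside every region used. Region and flank were compared by the exact McNemar test, two-sided. Pairs of the E-box CAGATG and the homeodomain site TAATTA were counted at gaps of 0 to 30 bp in both orientations, 62 arrangements in all, and each was compared with the mean over arrangements by an exact binomial test. P-values were adjusted by Benjamini-Hochberg within each family (16 lists, 22 sequences or 62 arrangements), with a threshold of 0.05. Intervals on shares are 95% Clopper-Pearson intervals and cover counting error only.

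Lists, definitions, tests and alternatives were fixed before the data were examined, as was the rule for named genes. It named 14 genes in every case (Shh, Lmbr1, Tbx5, Tbx4, Pitx1, Prrx1, Hoxd13, Hoxa13, Sox9, Gli3, Grem1, Fgf8, Fgf10 and Hand2). For each list it allowed the 3 genes with the highest signal at the promoter and the first 3 by alphabet without a promoter region. It also allowed the 10 genes with most distal regions, the 10 with most distal regions per 100 kb among territories of at least 50 kb, with ties broken by alphabet, and for the consensus sequences the 5 highest and 3 lowest ratios past the threshold and the controls HNF4, GATA and AP-1. Genes and sequences named beyond this rule were chosen after their values were seen.

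The alternatives were the other peak sets, each replicate's own list (leaving out the other replicate), a stricter threshold that kept the 50% of summits with the highest signal, a promoter window of 1000 bp, a distal limit of 5000 bp, assignment within 100 kb, no matching on territory, a flank window at a fixed 5 kb (5000 bp) without GC matching, windows of 100 bp, and other site definitions. The overlap list with CpG-matched random lists and a flank at random within 2 to 10 kb without GC matching were added after seeing the data.

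The tests were checked on simulated data of a simple kind. Every gene had the same chance of an open promoter, without the CpG differences between real lists. Region and flank windows were random bases of the same composition, without repeats. The shares of false calls hold for that setting and can be higher in the real data. A list of promoters set at 90% was recovered in 100% of 100 runs, with 0.4% of the other lists called. A list with distal counts raised 3 times was recovered in 95% of 40 runs, with 0% of the others called. These counts were drawn in proportion to territory, without clustering of regions, and the olfactory and vomeronasal list was left out. Smaller rises in distal counts were not simulated. Sequences placed in 5% of windows were recovered in 100% of cases over 20 runs with 0.625% of the others called, and a preferred spacing of 10 pairs was recovered in 100% of 20 runs with 0% of arrangements called before it was placed. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and blastn 2.17.0.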

Results

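Open chromatin was mapped by ATAC-seq in E11.5 mouse limb, the stage at which the limb bud has grown out and its skeleton is being laid down. The data consisted of 1 group of 2 biological replicates, pools of limbs from 109 embryos (replicate 1) and 88 embryos (replicate 2). The deposited values were peak lists without read counts, so the depth of each library is unknown, and positions are on mm10. With a single group, the comparisons that follow are between the replicates, between gene lists and between sequences within this tissue.

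The first comparison asked how far the replicates found the same open regions. Replicate 1 gave 8041 regions past the IDR threshold and replicate 2 gave 12433. Of the regions of replicate 1, 95.3% were found in replicate 2 (95% CI 94.8 to 95.8), against a mean of 0.979% for the same regions moved along the chromosomes. Of the regions of replicate 2, 61.4% were found in replicate 1 (95% CI 60.5 to 62.3, 0.635% when moved). With lists of equal length the shares were 80.1% and 79.6%. The promoters of Gli3, the transcription factor that mediates hedgehog signalling, and of Sox9, the main regulator of cartilage formation, were in the IDR lists of both replicates. The promoters of Hand2, a regulator of Shh in the posterior limb bud, and of Hoxd13, a digit patterning gene, were in that of replicate 2 and not in that of replicate 1.

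Regions with high signal were shared and those with low signal were often found in replicate 2 alone. In the top decile of replicate 2 by signal, 99.0% of regions were found in replicate 1, and in the bottom decile 19.1% were. The corresponding shares of replicate 1 were 100% and 84.1%. After merging, the lists held 12778 regions, of which 7604 (59.5%) were in both, 376 in replicate 1 alone and 4798 in replicate 2 alone. Promoters made up 57.5% of the regions of replicate 2 not found in replicate 1 and 82.8% of those found. Of the regions not found, 87.5% were in the overlap list of replicate 1, which has no IDR threshold.

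**Figure D1:**
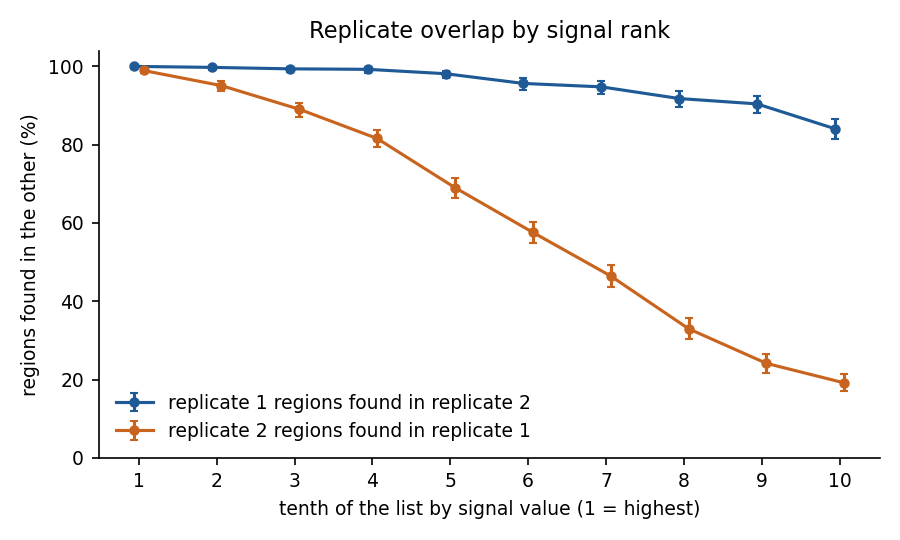
Share of the regions of each replicate found in the other (vertical axis, percent) by decile of signal within its own IDR list (horizontal axis, 1 is the highest), with 95% Clopper-Pearson intervals. The share fell from 99.0% to 19.1% in replicate 2 and from 100% to 84.1% in replicate 1.

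Both replicates together gave 13960 regions in the IDR list, with a median width of 996 bp and a total of 14.1 Mb (0.516% of the genome). Most were at the start of a gene. The share at promoters was 68.9% (95% CI 68.1 to 69.6), and 10408 of 21851 protein-coding genes (47.6%) had a promoter region. Promoter windows cover 1.04% of the genome, a 66.4-fold difference (two-sided exact binomial test, p rounded to 0 in double precision). That background is a share of bases and ignores the width of the regions, so it makes the difference too large. Regions moved along the chromosomes met a promoter in 2.39% of cases, a 28.8-fold difference. Distal regions numbered 3024 (21.7%, 95% CI 20.98 to 22.4), of which 61.6% were intergenic, 35.0% in introns and 3.37% in exons. The overlap list held 39587 regions, with 34.0% at promoters and 20543 distal. The promoter share was 80.4% in the list of replicate 1 and 73.0% in that of replicate 2.

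The next comparison asked whether genes of limb patterning had open promoters. Of 30 limb mesenchyme transcription factors, 17 (56.7%, 95% CI 37.4 to 74.5) had a promoter region in the IDR list, against 47.6% of the other genes. Of 33 genes of limb bud signalling, 14 (42.4%, 95% CI 25.5 to 60.8) had one, and of 9 HoxA and HoxD genes from the 9 to 13 groups, 5 had one. The overlap list held many more, with 28 of 30 transcription factors (93.3%, against 60.9% of the other genes), 28 of 33 signalling genes (84.8%) and 9 of 9 Hox genes (95% CI 66.4 to 100). No limb list differed from the other genes in the IDR list by Fisher's exact test (adjusted p = 0.415, 0.644 and 0.745), and all 3 had more promoter regions in the overlap list (adjusted p = 0.000321, 0.00895 and 0.0294). Limb promoters are rich in CpG, and against random lists matched on CpG none of these overlap-list differences passed a permutation test (adjusted p = 0.633, 0.593 and 1), while limb bud signalling fell below its matched lists in the IDR list (42.4% against 74.1%, permutation adjusted p = 0.0016).

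Among the transcription factors, the highest promoter signals in the IDR list were those of Pbx1, a cofactor of Hox proteins (11.2), Gli3 (7.99 at 13:15462528-15464073) and Tbx3, a T-box factor of the limb margins (7.23). Hand2 had a signal of 3.64 at 8:57320688-57321738. Tbx5, Tbx4, Pitx1 and Prrx1 were in the overlap list alone. These are Tbx5, which is needed for forelimb outgrowth (2.97 at 5:119834035-119834338), Tbx4 and Pitx1, which act in the hindlimb (3.64 at 11:85885778-85886633 and 2.96 at 13:55831141-55831707), and Prrx1, a marker of limb mesenchyme (2.45 at 1:163313336-163313847). Alx4, Irx5 and Lhx9 were also in the overlap list alone. Shox2 and Tfap2b had no promoter region in either list.

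In the signalling list, the highest promoter signals were those of Etv5 (11.1), Dusp6 (7.96) and Spry2 (7.12), all known targets of fibroblast growth factor signalling. Fgf10, the mesenchymal factor that maintains limb outgrowth, had a region at 13:118714207-118715462 (5.04) that was in neither replicate's own IDR list. Grem1, an antagonist of bone morphogenetic proteins, had one in the overlap list alone (3.18 at 2:113757565-113759368), as had Aldh1a2 and Cyp26b1, which make and degrade retinoic acid, and Bmp4. Shh, the signal of the polarizing region, and Fgf8, the signal of the apical ridge, had no promoter region in either list, and neither had Fgf4, En1 and Sp6.

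Lists of other cell types served to ask what else the tissue held. In the IDR list, 18 of 20 housekeeping genes had a promoter region (90%, adjusted p = 0.000588, Fisher's exact test). Fewer promoters than among the other genes were open for macrophages and photoreceptors (0 of 14 each, upper 95% limit 23.2%, adjusted p = 0.000588 by Fisher's exact test), erythroid cells (1 of 16, Tfrc, exact p adjusted to 0.002), surface ectoderm (1 of 15, Perp, exact adjusted p = 0.00306), liver (2 of 15, Foxa3 and Cebpa, exact adjusted p = 0.019), endothelium (3 of 16, Kdr, Erg and Egfl7, exact adjusted p = 0.047), and olfactory and vomeronasal receptors (2 of 1465, Vmn1r4 and Olfr94, p rounded to 0 in double precision). The regions of Foxa3 and Vmn1r4 also lay at the starts of Sympk and Nt5c3. In the overlap list, surface ectoderm (7 of 15, exact adjusted p = 0.363) and endothelium (7 of 16, exact adjusted p = 0.292) no longer passed the test. Endothelium did not pass with the stricter threshold (exact adjusted p = 0.0837), and erythroid cells, surface ectoderm and liver did not pass in the list of replicate 1 (exact adjusted p = 0.0521 each). With CpG-matched lists, macrophages, photoreceptors, erythroid cells, liver and housekeeping genes did not pass in the IDR list (permutation adjusted p = 1, 0.533, 1, 1 and 0.421).

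Cartilage and joint genes had a promoter region in 6 of 19 cases (exact adjusted p = 0.229), with high signal at Col11a1 (12.2) and Col9a1 (7.86), which encode cartilage collagens, and 5.07 at Sox9 (11:112781317-112782716). Acan, the main proteoglycan of cartilage, was in the overlap list alone. Cartilage passed in the list of replicate 2 alone (exact adjusted p = 0.0207, fewer than other genes). Muscle genes had one in 4 of 16 cases (exact adjusted p = 0.119, and 0.00963 for 0 of 16 in the list of replicate 1), namely Eya1, Six1, Met and Lbx1, which act in migrating muscle precursors. Nerve and glial genes had one in 2 of 11 cases (Mpz, at a start shared with Sdhc, and Isl1; exact adjusted p = 0.11), central nervous system genes in 3 of 15 (Foxg1, Syn1 and Neurod1; exact adjusted p = 0.0677) and heart genes in 4 of 14 (Myl4, at a start shared with Cdc27, Hcn4, Ryr2 and Tbx20; exact adjusted p = 0.229). Against CpG-matched lists, the nerve and the central nervous system lists were lower (18.2% against 51.2%, permutation adjusted p = 0.0491, and 20% against 74.4%, permutation adjusted p = 0.0016). In the overlap list the nerve list did not pass (45.5% against 68.1%, permutation adjusted p = 0.18) and the central nervous system list did (53.3% against 91.4%, permutation adjusted p = 0.0016).

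**Figure D2:**
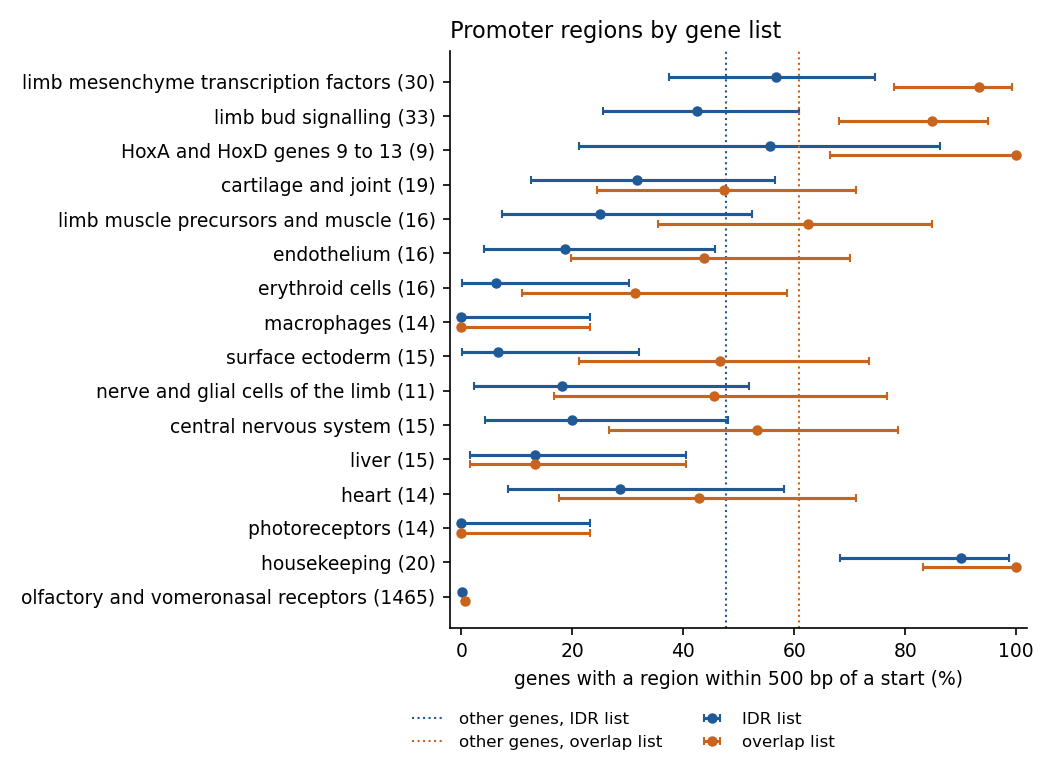
Share of the genes of each list with a region within 500 bp of a start (horizontal axis, percent) in the IDR list and in the overlap list, with 95% Clopper-Pearson intervals, list sizes in parentheses and the share of the other genes as dotted lines. Limb mesenchyme transcription factors stood at 56.7% and 93.3%, and housekeeping genes at 90% and 100%.

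Distal regions were then compared between gene lists, since limb genes are known to be controlled from far away. Genes of 2 limb lists had more distal regions than other genes with territories of the same length. In the IDR list the limb mesenchyme transcription factors had 0.933 distal regions per gene against 0.399 in random lists (2.34 times, 95% of random lists 0.167 to 0.733, permutation adjusted p = 0.0267), and limb bud signalling had 0.879 against 0.322 (2.73 times, 95% of random lists 0.121 to 0.606, permutation adjusted p = 0.016). In the overlap list the means were 5.90 against 3.02 (1.96 times, permutation adjusted p = 0.0016) and 4.30 against 2.33 (1.85 times, permutation adjusted p = 0.0032). The signalling difference passed in neither replicate's own list (1.296 times in replicate 2 and 0.922 times in replicate 1, permutation adjusted p = 0.997 and 1) and was 1.76 times in the larger IDR list (permutation adjusted p = 0.266). The difference of the transcription factors was 2.65 times in the list of replicate 2 (permutation adjusted p = 0.0144) and 1.66 times in that of replicate 1, where it did not pass (permutation adjusted p = 1). Neither list passed with the stricter threshold (2.14 and 2.23 times, permutation adjusted p = 0.0811 each) or beyond 5000 bp (2.06 and 2.45 times, permutation adjusted p = 0.142 and 0.0592), and signalling did not pass within 100 kb (1.94 times, permutation adjusted p = 0.187).

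Cartilage and joint genes had 2.26 times as many distal regions as random lists in the IDR list, which did not pass (permutation adjusted p = 0.278), and 1.93 times as many in the overlap list, which did (permutation adjusted p = 0.0352). Olfactory and vomeronasal receptors had fewer, 0.0184 per gene against 0.0579 (0.318 times, permutation adjusted p = 0.0032 from the smallest p the permutations can give). The other 12 lists did not pass, and their ratios ran from 0 (Hox genes, liver, heart and photoreceptors) through 0.47 (nerve and glia), 0.822 (housekeeping), 1.24 (central nervous system), 1.36 (macrophages), 1.38 (muscle) and 1.39 (surface ectoderm) to 2.17 (erythroid cells) and 2.19 (endothelium).

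**Figure D3:**
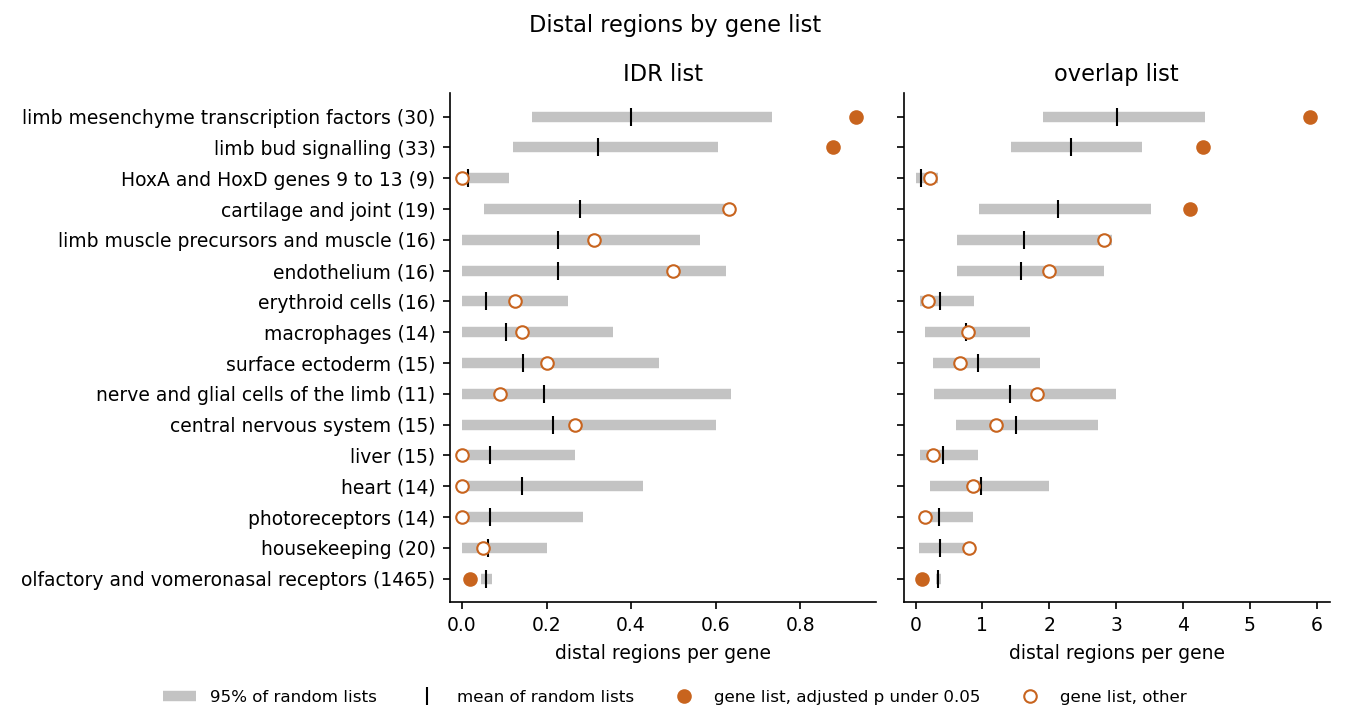
Mean number of distal regions per gene (horizontal axis) for each gene list in the IDR list and in the overlap list, with the mean and the central 95% of 10000 random lists matched on territory length. Limb mesenchyme transcription factors (0.933 against 0.399 in the IDR list) and limb bud signalling (0.879 against 0.322) lay above the random lists in both panels.

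Of the genes named in every case, Tbx4 had 3 distal regions in the IDR list, the nearest to its start at 11:85875920-85876832. Gli3, Hand2 and Grem1 had 2 each, at 13:15052585-15053525 and 13:15395078-15395700, at 8:57328237-57329515 and 8:57353407-57354277, and at 2:113674579-113675452 and 2:113693380-113693802. The Grem1 regions lay in introns of the neighbouring gene Fmn1. Sox9 had 1 at 11:112010939-112011170, 771 kb from its start, and 16 in the overlap list. Pitx1 had 1 at 13:55962991-55963585. Fgf10, Tbx5, Prrx1, Shh and Fgf8 had none in the IDR list and 4, 3, 2, 1 and 1 in the overlap list.

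Across all genes, 2242 had at least 1 distal region in the IDR list and 30 had 5 or more. The highest counts were at Smad7, an inhibitor of transforming growth factor signalling (9), Tns1 (9), Gas1, a hedgehog co-receptor (7), Gm21860 on the Y chromosome, Lrig3, Mpped2 and Zmiz1 (7 each), and 4930558K02Rik, Boc, another hedgehog co-receptor, and Ets1 (6 each). Per 100 kb of territory the highest values were at Klrb1c (7.75), Mrpl23 (6.39) and Akna (5.99), followed by Trim27, Nepro, Ptma, Synpo, Shf, Ddit4 and Actg1 (4.79 to 5.39).

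The Hox clusters and Lmbr1 were examined as loci of limb patterning. The IDR list held 7 regions in the HoxA cluster, 5 in HoxC, 2 in HoxD and 1 in HoxB, or 0.665, 0.432, 0.207 and 0.0575 per 10 kb. The overlap list held 17, 13, 15 and 8, and it covered the promoters of 9 of 9 HoxD genes, 9 of 11 HoxA genes, 4 of 9 HoxC genes and 3 of 10 HoxB genes. Promoter regions in the IDR list included those of Hoxd13 (2:74667751-74668757, signal 4.36), Hoxa13 (6:52260669-52261305, 4.04), Hoxa9 (3.46), Hoxd11 and Hoxa11. Hoxa10, Hoxd9 and Hoxd12 were in the overlap list and in no IDR list of both or single replicates, and Hoxd10 was in the overlap list and in the IDR list of replicate 2 (4.63). The IDR list of replicate 1 held 1 region in the HoxD cluster and none in the others, and that of replicate 2 held 5 in HoxA, 2 in HoxC, 2 in HoxD and none in HoxB.

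**Figure D4:**
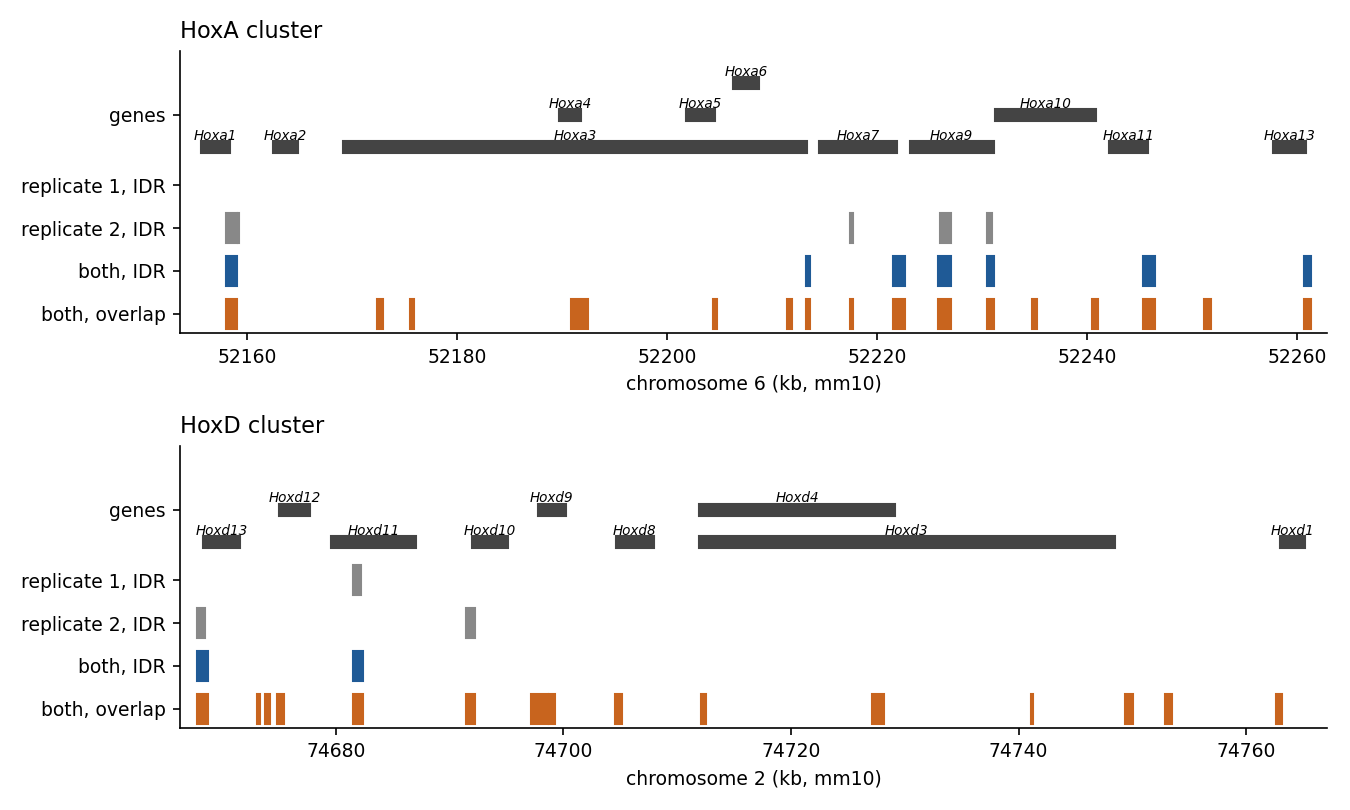
Map of the HoxA and HoxD clusters (horizontal axis, position in kb on mm10) with the genes and the regions of 4 peak lists. The IDR list of both replicates held 7 regions in HoxA and 2 in HoxD, and the overlap list 17 and 15.

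Lmbr1, the gene whose introns host the limb enhancer of Shh, had a promoter region in every list (5:29377687-29379032, signal 9.65 in the IDR list). No region lay in its introns in the IDR list. The overlap list held 1, at 5:29315104-29315593 in intron 5 of a transcript with 17 exons, with a signal of 3.89 and a −log10 p of 12.9, 848 kb from the start of Shh. In the overlap lists of the single replicates, replicate 2 held 2 intronic regions and replicate 1 held none.

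Distal regions were searched for binding sequences of known classes of transcription factor. Of 22 consensus sequences, 10 were more frequent in the 3024 distal windows than in their GC-matched flanks (mean GC content 54.8% in the windows and 53.47% in the flanks). The highest ratios were those of CTCF, the insulator protein (13.2 times, 3.94% of windows against 0.298%, adjusted p = 1.33e-24, exact McNemar test), SP/KLF (3.30 times, adjusted p = 6.90e-23), PBX-HOX (3.10 times, 5.13% against 1.65%, adjusted p = 3.15e-13), TEAD (2.88 times, adjusted p = 2.18e-09) and HOX13, the sequence of the digit Hox proteins (2.61 times, adjusted p = 1.50e-05). The general homeodomain site TAATTA was 2.31 times as frequent (exact McNemar, adjusted p = 3.61e-09), and the E-boxes CATCTG of TWIST and HAND proteins and CAGCTG of myogenic factors were 1.47 and 1.79 times as frequent (adjusted p = 7.54e-13 and 6.42e-28). RUNX and SOX sites were 1.98 and 1.27 times as frequent (exact adjusted p = 0.000202 and 0.0256). PITX sequences were less frequent, at 0.596 times (exact adjusted p = 0.00418). The control GATA was also less frequent, at 0.408 times (exact adjusted p = 0.00115), so not every control was without a difference. The other controls, HNF4 (1.33 times) and AP-1 (1.02 times), did not pass the exact McNemar test (exact adjusted p = 0.966 and 1).

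Against a flank taken at random from the same 2 to 10 kb without GC matching, a test chosen after the result was seen, the homeodomain site (0.902 times, exact adjusted p = 0.494), HOX13 (1.26 times, exact adjusted p = 0.342), RUNX (1.25 times, exact adjusted p = 0.281) and SOX (1.07 times, exact adjusted p = 0.542) did not pass, so these results depended on GC matching. The 2 backgrounds differed in AT-rich and GC-rich sequence. TAATTA was in 2.12% of the matched and 5.42% of the random flanks, and the SP/KLF sequence in 2.45% and 0.595%. GLI (10 windows against 1, exact adjusted p = 0.0258) and NRF1 (8 against 0, exact adjusted p = 0.0191) passed against the random flank and not against GC-matched flanks. Against a flank at a fixed 5 kb, the homeodomain site stood at 0.787 times (exact adjusted p = 0.0618), HOX13 at 1.07 (adjusted p = 0.888), RUNX at 1.34 (adjusted p = 0.119), SOX at 0.988 (adjusted p = 0.942) and PBX-HOX at 1.36 (adjusted p = 0.0304), while SP/KLF stood at 11.6 and CTCF at 39.7, and NRF1 passed (8 windows against 0, exact adjusted p = 0.0215). In the overlap list CTCF stood at 27.9 times, HOX13 at 2.03 and PBX-HOX at 2.06, and 5 sequences newly passed, namely GLI (1.98 times, from 0.769 in the IDR list, exact adjusted p = 0.000474), NFI (6.0 times, 18 windows against 3, exact adjusted p = 0.00234), TBX (1.33 times, exact adjusted p = 0.0036), MEIS (1.06 times, exact adjusted p = 0.0121) and the control AP-1 (1.14 times, exact adjusted p = 0.017). NRF1 newly passed in the larger IDR list (11 windows against 1, exact adjusted p = 0.0127) and in the list of replicate 2 (7 against 0, exact adjusted p = 0.0298). PITX passed in neither replicate's own list (exact adjusted p = 0.392 in replicate 2 and 0.525 in replicate 1), and TEAD, SOX, GATA and RUNX did not pass in that of replicate 1 (adjusted p = 0.259, 0.281, 0.32 and 0.0796). In windows of 100 bp, SOX and GATA (exact adjusted p = 0.0547 each) and RUNX (exact adjusted p = 0.0544) did not pass.

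The last comparison asked whether E-box and homeodomain sites kept a fixed distance, as bHLH and homeodomain proteins of mesenchyme are known to bind DNA together. A single arrangement stood out, CATCTG followed by TAATTA with 4 bp between them. It made up 6 of the 16 pairs in the IDR list (23.3 times the mean over 62 arrangements, adjusted p = 7.61e-06, exact binomial test) and 17 of the 109 pairs in the overlap list (9.67 times, adjusted p = 1.67e-10, exact binomial test). The flank windows held 0 of 1 pair and 0 of 14 pairs in this arrangement, too few pairs to tell whether the flanks lack it. The 6 sites of the IDR list were nearest to the starts of Spsb1, 4933402N22Rik, Olfr514, Cpn2, Robo2 and Rcan2, with those at 16:74093345-74093360 and 17:43991324-43991339 in introns of Robo2 and Rcan2. The list of replicate 2 held 4 of 10 pairs in this arrangement (24.8 times, adjusted p = 0.000815, exact binomial test), and that of replicate 1 held 1 of 5 (12.4 times, adjusted p = 0.968, exact binomial test). The E-box CAGCTG, run as an alternative site definition, also peaked at 4 bp, with 5 of 15 pairs (10.3 times, adjusted p = 0.00248, exact binomial test). It reads the same on both strands and has a single orientation. Its ratio is therefore to a mean over fewer arrangements than 62 and cannot be set beside those of CATCTG. A peak at 4 bp was thus not particular to CATCTG.

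**Figure D5:**
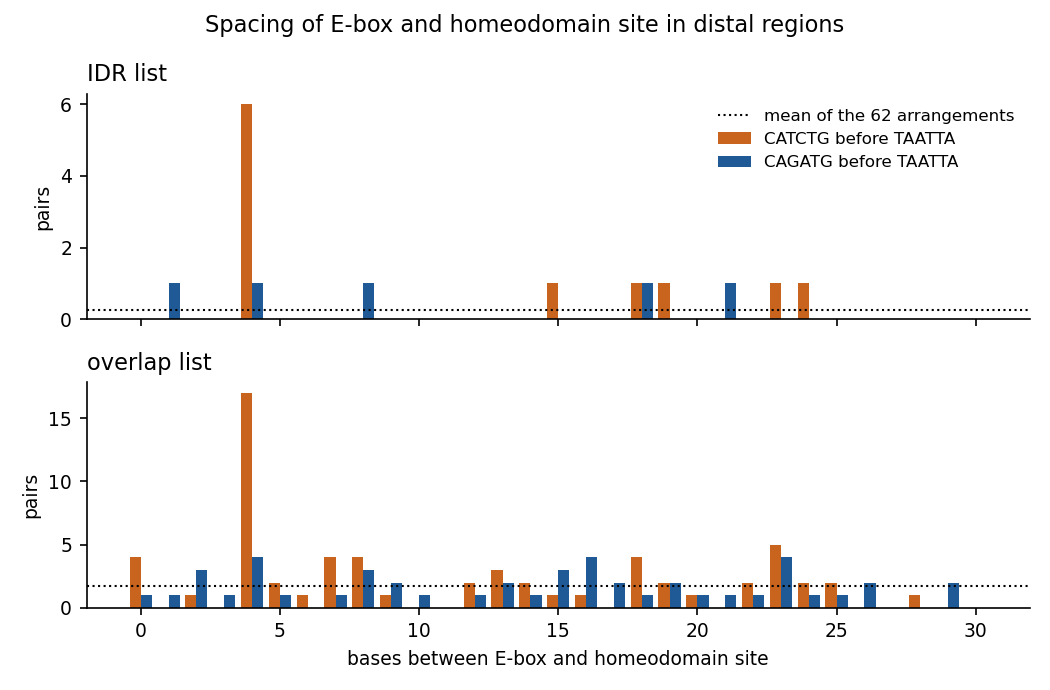
Number of pairs of E-box and homeodomain site (vertical axis) by the number of bases between them (horizontal axis) and orientation, in distal windows of the IDR list and of the overlap list, with the mean over arrangements as a dotted line. CATCTG before TAATTA at 4 bp held 6 of 16 pairs and 17 of 109 pairs.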

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

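Past the IDR threshold, 72 regions on the chromosomes used were in the ranked list of both replicates and absent from the IDR list, a signal outside the regions that the comparisons used. Of the 83324 ranked summits, 38644 were at or above the threshold, 38393 of these were in the IDR list and 251 were not. Of these absent summits, 77 lay on sequences other than the chromosomes used, also a signal outside the comparisons.

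The absent regions had a median −log10 p of 92.1 against 52.9 in a random sample of 1000 kept regions, with a median signal of 6.93 against 6.55. The highest −log10 p was 6330 at 1:24611587-24616165, where the signal was 3.56. Copies of mitochondrial DNA in the nuclear genome could draw such reads, and the region on chromosome 1 matched mitochondrial DNA over 100% of its length, but it was 1.39% of the absent regions (1 of 72), which argues against mitochondrial copies as the explanation for the rest. A median 31-mer count of 2 or more in the genome was found in 26.4% (19 of 72), against 1.4% of the kept sample, and a count of 10 or more in 5 of the 72. Whether repeated sequence accounts for the absent regions as a whole cannot be told apart from a filter of another kind, since 52 of them were in neither class and copies collapsed in the assembly are not counted. The sources used here do not describe a filter, and no biological explanation was tested because there was 1 group.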

How the results depend on the processing

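No paired analysis was possible because there was 1 group of 2 pools. Depth could not be weighed, since the lists hold no counts. The overlap list with CpG-matched lists and the random flank without GC matching were chosen after seeing the data. Unless a cause is named, the cause was not tested. Of the alternatives to results that answer a comparison, 54 kept their direction and side of the threshold (or their value), 21 moved, 9 no longer passed, 3 newly passed and 11 reversed. For single lists, sequences and loci these counts were 247, 15, 27, 8 and 39. HNF4 had no value in windows of 100 bp.

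The share of replicate 1 regions found in replicate 2 was 90.4% at 50% reciprocal overlap, 79.4% with the overlap lists of the replicates, 96.05% with the stricter threshold and 80.1% at equal length, and that of replicate 2 in replicate 1 was 58.5%, 56.8%, 60.5% and 79.6%. The count of regions was 39587 in the overlap list, 8041 to 12433 without either replicate, and 38393 when each summit was counted, by construction. The share at promoters was 65.4% in the larger IDR list, 34.0% in the overlap list, 73.0% to 80.4% without either replicate, 70.9% with the stricter threshold and 69.9% with a 1000 bp window.

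For promoters, in percentage points over other genes, limb mesenchyme transcription factors (9.05 in the IDR list) stood at 32.5 in the overlap list, -9.10 with the stricter threshold, -14.5 against CpG-matched lists and -9.41 to -1.77 without either replicate. Limb bud signalling (-5.22) stood at 24.0 in the overlap list, -15.5 with the stricter threshold, -31.7 against CpG-matched lists and -17.6 to -14.8 without either replicate. Hox genes (7.93) stood at 39.1, -23.5 with the stricter threshold, -22.0 against CpG-matched lists and -21.6 to -11.8 without either replicate. Muscle (-22.6) stood at 1.60 in the overlap list and 1.99 there against CpG-matched lists, where erythroid cells stood at 15.6 and 2 lists passed in place of 8.

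For distal regions, as ratios to random lists, limb mesenchyme transcription factors stood at 2.06 beyond 5000 bp, 2.14 with the stricter threshold and 1.66 to 2.65 without either replicate. Limb bud signalling stood at 1.76 in the larger IDR list, 2.45 beyond 5000 bp, 2.23 with the stricter threshold, 1.94 within 100 kb and 0.922 to 1.296 without either replicate. The number of lists past the threshold was 1 beyond 5000 bp, 1 with the stricter threshold and 1 to 2 without either replicate, in place of 3. The remaining reversals were in lists that passed in no setting. In the larger IDR list these were central nervous system 0.497, erythroid cells 0.865 and housekeeping 2.69, and in the overlap list Hox genes 2.84, central nervous system 0.802, erythroid cells 0.516, housekeeping 2.20, nerve and glia 1.28 and surface ectoderm 0.714. Without matching, erythroid cells stood at 0.909. Beyond 5000 bp, muscle stood at 0.951 and macrophages at 0.833. With the stricter threshold, central nervous system stood at 0 and macrophages at 0.767. Within 100 kb, housekeeping stood at 1.58, muscle at 0.798, nerve and glia at 1.44 and photoreceptors at 1.82. Without either replicate, central nervous system and erythroid cells stood at 0, housekeeping at 2.39 to 3.19, macrophages at 0 to 0.8998 and surface ectoderm at 0 to 1.89.

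For consensus sequences, a fixed flank at 5 kb without GC matching gave AP-1 at 0.980, SOX at 0.988 and the homeodomain site at 0.787. A random flank without GC matching gave AP-1 at 0.971 and the homeodomain site at 0.902, and SOX kept its direction there. AP-1 stood at 0.970 in the larger IDR list and 0.743 to 0.952 without either replicate, and HNF4 at 0.727 in the larger IDR list and 0.962 in the overlap list. The spacing of 4 bp stood at 12.4 to 24.8 times without either replicate, and at 12.4 it rested on 1 of 5 pairs in the list of replicate 1.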

Other observations

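The test with gene sets matched on −log10 p and that of other words at the gap and side of the E-box were chosen after the result was seen. Among the 72 genes of the 3 limb lists, 65 had a promoter region in the overlap list, 36 of them also in the IDR list and 29 in the overlap list and not in the IDR list. The median −log10 p of the 65 regions was 20.5, against 52.0 for all genes with a region and 94.4 for housekeeping genes. By decile of −log10 p over all genes, the lowest 3 deciles held 10, 20 and 16 of the limb genes. The share of genes also in the IDR list was 0.301% in the lowest decile, 21.9% in the next, 72.4% in the third and 91.5% in the fourth.

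The limb genes may be missing from the IDR list because that list keeps strong regions and limb promoters carry weaker ones. Their median of 20.5 was at percentile 0 of 10000 random gene sets matched on CpG (median 53.6, central 95% 39.7 to 72.8), but the test could hardly come out otherwise, since membership of the IDR list follows −log10 p closely, so this explanation stays open. A cause beyond −log10 p that keeps limb genes out was argued against, since 36 in the IDR list was at percentile 86.4 of 10000 gene sets matched on −log10 p (median 33, central 95% 28 to 38). At a given −log10 p, limb genes were thus in the IDR list about as often as genes at large. Why their −log10 p was low was not tested. Loss through the smaller list of replicate 1 was not decided. Of the 29 genes, 6.90% (2 of 29) were in the IDR list of replicate 2 and not in that of replicate 1, and 27 were in neither. The 29 were chosen as absent from the IDR list, which was longer than that of replicate 2 (13960 against 12433 regions). A low share in the list of replicate 2 could therefore arise whatever the cause. How often genes absent from the IDR list are in that of replicate 2 was not counted. A low share of cells using each promoter in a mixed tissue remains open as a hypothesis that these data do not test.

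The spacing of 4 bp between E-box and homeodomain site could come from copies of a repeat or from base composition. Of the 17 windows of the overlap list with this arrangement, 0% matched another over 50 bp or more, which argues against copies of one repeat element. Of 179 other words with the same bases as the E-box, 0% reached 17 pairs at any gap and side, and the highest count was 8. This count cannot decide for the 65 words that had fewer than 17 pairs in all. The others also had fewer pairs in all than the E-box (at most 73, for TGCAGA, against 109), which makes 17 harder to reach. As a share of their own pairs, AGATGC (8 of 43, 18.6%) and GCAGTA (5 of 31, 16.1%) exceeded the E-box (17 of 109, 15.6%). AGATGC peaked at 5 bp on the side of the E-box, where its pairs can be the E-box arrangement read from the next base of CAGATG. It may therefore not be an independent word. GCAGTA peaked at 14 bp, and its share is the highest over all gaps and sides from few pairs. These shares therefore cannot decide on base composition in general, which stays open. At the gap and side of the E-box itself the 179 words together had 1.62% of their pairs (72 of 4448, 95% CI 1.27 to 2.03). The E-box had 15.6% there (95% CI 9.36 to 23.8). That gap and side were chosen as the peak of the E-box, so its share could hardly be the lower. The contrast shows that the other words as a group had few pairs there. It cannot decide on base composition at that distance from the homeodomain site. Joint binding of a bHLH and a homeodomain protein also stays open, as a hypothesis found on these data and not tested by binding.

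Of the 72 kept regions with the highest signal, 6 (8.33%) matched mitochondrial DNA over more than 50% of their length.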
